A study of Zea mays with 27 samples.

How the data were processed

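Above-ground tissue of 14-day maize seedlings of B73, Mo17 and their F1 was measured on 27 two-colour cDNA arrays. Per the labels, 10 replications were grown and 9 analysed, 6 seedlings were pooled per genotype and replication, seed came from 3 sources per genotype, about 500 µg of total RNA went into each mRNA isolation and 2 µg of mRNA into each labelling. Each replication used a loop of 3 arrays covering every pair of genotypes with dyes balanced. The labels name 1 channel of array 1 (F1 in Cy3) and 1 of array 17 (Mo17 in Cy5). The genotypes of the other channels were not inferred from array order or from the values, and the 25 unlabelled arrays entered no comparison between groups.

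The deposited table holds 1 signed ratio per spot and array, and the values themselves show that the authors deposited natural log ratios. Differences between repeated values within an array match those that small multiples of the lowest signal would give under the natural log: 59 pairs matched on 20 arrays within 2e-06, against 0 pairs for log2, 3 for log10 and 5 for a log to base 3, over 18 multiples tried. The base was settled from this after an earlier reading had left it open. The direction of the ratio, the background correction and the within-array normalization are not given in the sources used here. Array medians ran from -0.162 to 0.229 and array means from -0.0460 to 0.0657. The values carry no signal level, so depth and detection could not be assessed for single spots. On each array the most frequent exact value was held by 10 to 584 spots. That value lay within 0.4 of 0 on 16 arrays and farther from 0 on 11, from -4.51 on array 12 to 4.71 on array 19. It is read here as the mark of spots with both channels at the lowest signal, which is an inference. Under that reading, with no further adjustment, pairs of repeated values would lie evenly about it. They did not on these arrays: all 19 such pairs, on 8 of the 11 arrays, had their midpoint above it, for example at -4.22 and -3.59 against -4.51 on array 12, and the cause was not tested. For 15 of the 19 the midpoint was still nearer to the most frequent value than to 0. The other 3 of the 11, arrays 6, 19 and 21, gave no pair.

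Probes were named through the platform's annotation. It listed 1630 probes, of which 23 had several genes and were not named, and 1607 had 1 gene and a value. The other 16673 measured probes are unnamed here. Classical gene names came from the RefSeq annotation of Zm-B73-REFERENCE-NAM-5.0, matched by gene ID for 1320 of the 1607 probes. No coordinates are given, since the table names no genome build. The annotation gave 221 probes to a single gene, MNB1b, and the next most frequent gene had 26. That assignment looks doubtful and was not checked. Without it, 1386 probes stand for 531 genes. The layout of spots on the slide was not used. Empty spots recurred every 400 spot numbers, with a correlation of 0.825 at that lag, so runs of 400 consecutive numbers, 48 in all, stood in for position.

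Each array was centred on its median. A probe's spread was its interquartile range over the 27 arrays, and a probe was wide above 3 times the median range. Pearson correlations were taken across probes for all pairs of arrays. Components were counted up to the first that did not exceed the highest share of the same component in 100 matrices with each probe's values permuted over the arrays. On each labelled array, probes outside the range of the other 26 arrays were counted. Each list's median range was set against 10000 random lists of as many probes, not matched on level because the values are ratios. These were drawn from all 18303 measured probes, while list members are named probes. Named probes were less often wide (2.24% against 4.60% of all), and no random lists of named probes alone were drawn. No test between groups was made and no p-value was computed. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.

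The lists, the cutoffs, the statistics of the main results and most alternatives were fixed before the data were examined. Named genes followed a fixed rule: the 15 widest named probes, the 5 highest and 5 lowest on each labelled array, and the widest and narrowest member of each list. Lists were matched by gene symbol alone, since the tables gave no gene descriptions. The split by most frequent value, the ranges with those values left out, the centring of runs, the removal of each array in turn, the addition of hsp70-4 to the heat shock list, the named probes that never held the most frequent value, the correlation between probes of the same gene, the leading profile and its tests, the comparison of the last 2 runs of array 1 and the test of wide probes by position were chosen after seeing the data.

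The statistics were tested on simulated data made from the 18303 probes, with values permuted over the arrays and 200 probes given known genotype levels. In the first simulation most of the changed probes had the F1 at the midparent. The component count found 1 of the 2 simulated dimensions, and 47 of 95 probes changed by 1 natural-log unit and 98 of 99 changed by 2 were called wide. A second simulation, with the F1 level independent of the midparent, was added after that outcome. It gave both dimensions, 84 of 95 and 99 of 99. There the F1 and 1 parent could differ by 2 times the set size, which no pair did in the first simulation. The counts of wide probes from the 2 simulations are therefore not for the same size of change. The component count can therefore miss a dimension, and the wide call misses many changes of 1 unit. With no effect added, 0 components were counted and a median of 7.41% of probes lay outside the other arrays. Both follow from permuting values over the arrays, which also removes any structure along the runs. They do not test for false components in data such as these. Of 40 random lists, 38 fell within the central 95%, and 35 of 40 lists made narrower fell below it.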

Results

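Transcript levels in the above-ground parts of maize seedlings were compared among the inbred lines B73 and Mo17 and their F1 hybrid, to ask how the hybrid stands relative to its parents. Seedlings were harvested at 14 days and 6 were pooled for each genotype in each replication. The series holds 27 two-colour cDNA arrays, 3 for each of 9 replications, and each array set RNA labelled with Cy3 against RNA labelled with Cy5. The labels name the genotype of 2 of the 54 channels: F1 in Cy3 on array 1 and Mo17 in Cy5 on array 17. The other 25 arrays carry no genotype label and were placed in no group, so no contrast between B73, Mo17 and the F1 was tested. Each value is a natural-log ratio of an array's channels, with its direction unknown, so a value above 0 is not assigned to either genotype on the array. Of 19200 spots, 18303 had a value on all 27 arrays and 897 had none on any. The table used here named 1 gene for 1607 of the measured probes, which stand for 532 genes. The number of arrays limits the precision of every value below.

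With each array centred on its median, the widest spread among named genes belonged to bt1 (brittle1), which carries ADP-glucose into endosperm plastids and whose probe 16185 had an interquartile range of 4.30 natural-log units over the 27 arrays. The derlin gene der4 (probe 3128) followed at 4.26, GRF13 (probe 10328) at 4.12 and the superoxide dismutase gene Sod4A (probe 12090) at 4.11. The phosphoenolpyruvate carboxylase gene pep7 (probe 7594) had a range of 3.87 and the calnexin gene CNX (probe 4445), an endoplasmic reticulum chaperone, 3.50. Each range is that of 1 probe and need not hold for its gene: another pep7 probe (15338) had 0.659. The peroxidase gene PER2 (probe 4264) reached 3.09, the glutathione transferase gene gst18 (probe 5088) 2.92 and KIN9 (probe 15403) 2.66. A probe for 4-coumarate-CoA ligase (728), an enzyme of phenylpropanoid synthesis, had 2.65, and a haemoglobin probe (16265) had 2.59. The nicotianamine synthase gene nas1 (probe 1157) had 2.54, LOC542286 (probe 17492) also 2.54, the recombinase gene rad51a (probe 11969) 2.46 and the terpene synthase gene TPS9 (probe 8799) 2.43. The order at the top depends on the setting: bt1 fell to 3.50 both with runs centred and with each array divided by its median absolute deviation, where der4 had 4.42 and 4.81. All 15 of these probes held their array's most frequent exact value on 1 to 8 arrays, a value shared by 10 to 584 spots of an array.

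**Figure D1:**
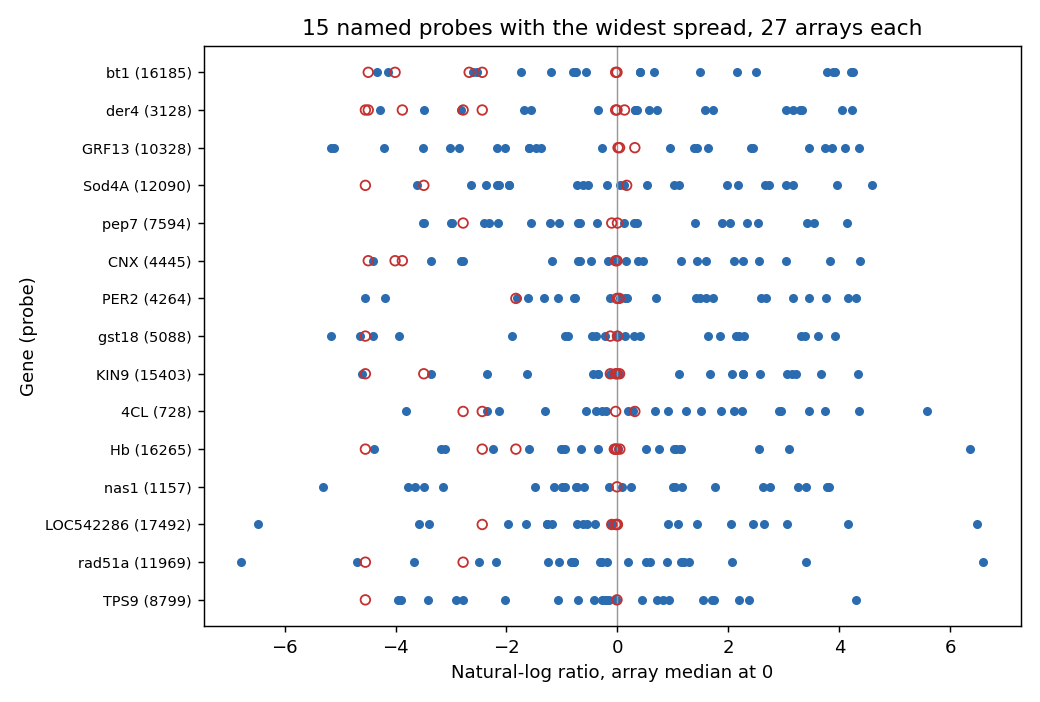
Natural-log ratios of the 15 named probes with the widest spread, each array's median set to 0; each point is 1 of the 27 arrays and an open circle marks the array's most frequent exact value. The probes reached interquartile ranges of 2.43 to 4.30 and every probe has at least 1 open circle.

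Over all 18303 measured probes, the median interquartile range was 0.470, a 1.60-fold span. A total of 842 probes (4.60%), among them 36 probes of 35 named genes, were wider than 3 times that median. Of the 842, 620 (73.6%) held the most frequent value on at least 1 array, against 590 of the 17461 other probes (3.38%). Among named probes that never held it, which were singled out after the values were seen, the widest was the cystatin gene cpi2 (probe 11154), at 2.41. The glutamine synthetase gene GLN6 (probe 1594) followed at 2.16, the cysteine protease gene mir3 (probe 18879) at 2.13 and the cystatin gene psei1 (probe 11718) at 1.77. A probe for the transcription factor gene WRKY1 (6419) had a range of 1.59, with values above 0 on 26 of the 27 arrays. Its range was 1.01 with each array divided by its median absolute deviation and the result brought back to the scale of the main median. If the ratio ran the same way on every array, dye-balanced loops would not give a genotype difference 1 sign on 26. The 5 WRKY1 probes that never held the most frequent value had a median correlation of -0.054 with runs centred. Without the probes that held the most frequent value, 250 probes were wider than 3 times their own median, and a cutoff of 2 times the median took in 2161 of all probes.

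**Figure D2:**
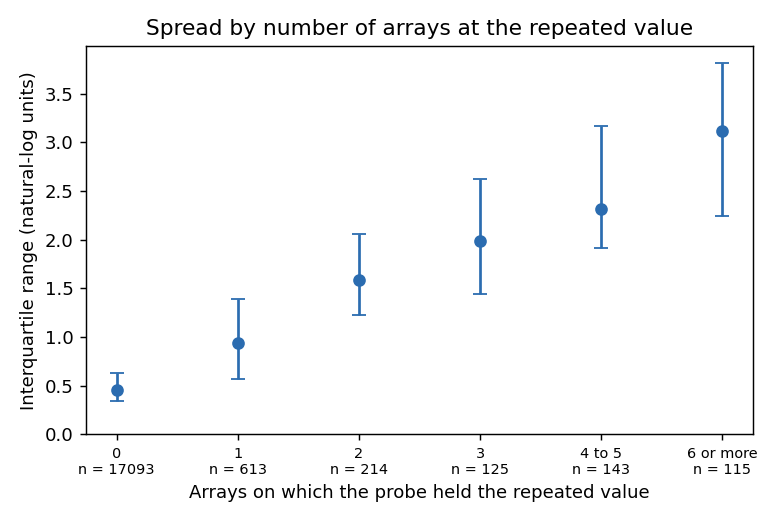
Interquartile range over the 27 arrays, in natural-log units, for probes grouped by the number of arrays on which they held the array's most frequent exact value; points are medians and bars run from the lower to the upper quartile of probes. The median is 0.455 for the 17093 probes that never held it and 3.12 for the 115 probes that held it on 6 or more arrays.

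The listed genes for cytosolic ribosomal proteins varied little over the arrays. Their 58 probes, of 11 genes, had a median interquartile range of 0.337, and 53 of them lay below the median of all probes. An rpl17 probe (11428) was the narrowest at 0.170, and a probe for the acidic protein gene rpp2 (1646) was the widest at 0.729. The list's median lay at percentile 0 of 10000 random lists of 58 probes. Those lists were drawn from all measured probes, most of them unnamed, and named probes were less often wide. With 1 probe per gene, a choice that favours wide probes, it lay at percentile 12.1. The fixed symbols left out other measured ribosomal protein genes, among them RPL27A, RP-P0, rpp3, rps6-2, rpp2b and rpp1a. These were not added, so the list does not stand for all such genes. Heat shock genes hsp18a and hsp22 had a median of 0.916 over 5 probes, at percentile 98.5, with an hsp18a probe (10727) at 1.06 and an hsp22 probe (15762) at 0.223. The percentile was 97.3 with each array divided by its median absolute deviation, 92.5 without probes that held the most frequent value and 88.4 with 1 probe per gene. With the 12 probes of hsp70-4, which the fixed symbols had left out, added after the values were seen, the heat shock median was 0.446 at percentile 35.8. The hsp70-5 gene, which the symbols had also left out, was not added. These 2 of the 8 lists with at least 5 probes lay outside the central 95% of random lists.

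Tubulin genes had a median of 0.425 over 45 probes of 10 genes, at percentile 12.2, or 1.42 with each run of 400 consecutive spot numbers centred and 80.2 with 1 probe per gene. That last setting takes each gene's probe with the largest median size, which favours wide probes, while the random lists took any probe. Percentiles with 1 probe per gene are therefore raised by the choice of probe. The tubulin probes ran from a TUA1 probe (9744) at 0.176 to a tub3 probe (14980) at 1.11. The 28 probes for glutathione transferases and catalases had a median of 0.480, at percentile 58.1, or 96.4 with 1 probe per gene and 41.5 to 73.6 under the other settings, from a gst10 probe (12403) at 0.232 to gst18 at 2.92. Cellulose synthase and expansin genes had 0.431 over 19 probes, at percentile 26.4, or 67.8 with each array divided by its median absolute deviation, 72.0 with quantile normalization, 59.9 with runs centred and 93.1 with 1 probe per gene, from an expa2 probe (6065) at 0.250 to an EXPB9 probe (16881) at 1.22. The carbon fixation list, with genes for malic enzyme, malate dehydrogenase, the small subunit of Rubisco and Rubisco activase, had 0.475 over 6 probes, at percentile 49.9, or 40.03 to 57.07 under the other settings. Its ends were a mdh6 probe (6174) at 0.383 and a rbcS probe (16448) at 0.624. The aquaporin gene tip1 had 0.414 over 7 probes, at percentile 27.4, or 15.3 to 66.8 under the other settings, from 0.244 (probe 1722) to 0.586 (probe 4066). The his1 gene for histone H1 had 0.424 over 5 probes, at percentile 34.5, or 14.97 with runs centred and 87.7 with 1 probe per gene, from 0.191 (probe 8996) to 0.910 (probe 12226).

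The remaining 4 lists with measured probes held 2 or 3 probes each. The photosystem I genes psaH (probe 2377) and psaN (probe 3964) had ranges of 0.736 and 0.520. The defence genes pr5 (probe 7176) and prp2 (probe 15672) had 1.02 and 0.871. In the phenylpropanoid list, both ends were probes of the phenylalanine ammonia-lyase gene pal3, at 0.872 (probe 13635) and 0.667 (probe 17617). The list of seed markers held the 27-kDa gamma zein gene gz27 (probe 18260), at 1.03, and 2 probes of a haemoglobin gene that shares the symbol GLB1 with a seed globulin, at 1.44 (probe 12334) and 2.59 (probe 16265). No measured probe was matched to the organelle or transposon lists.

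**Figure D3:**
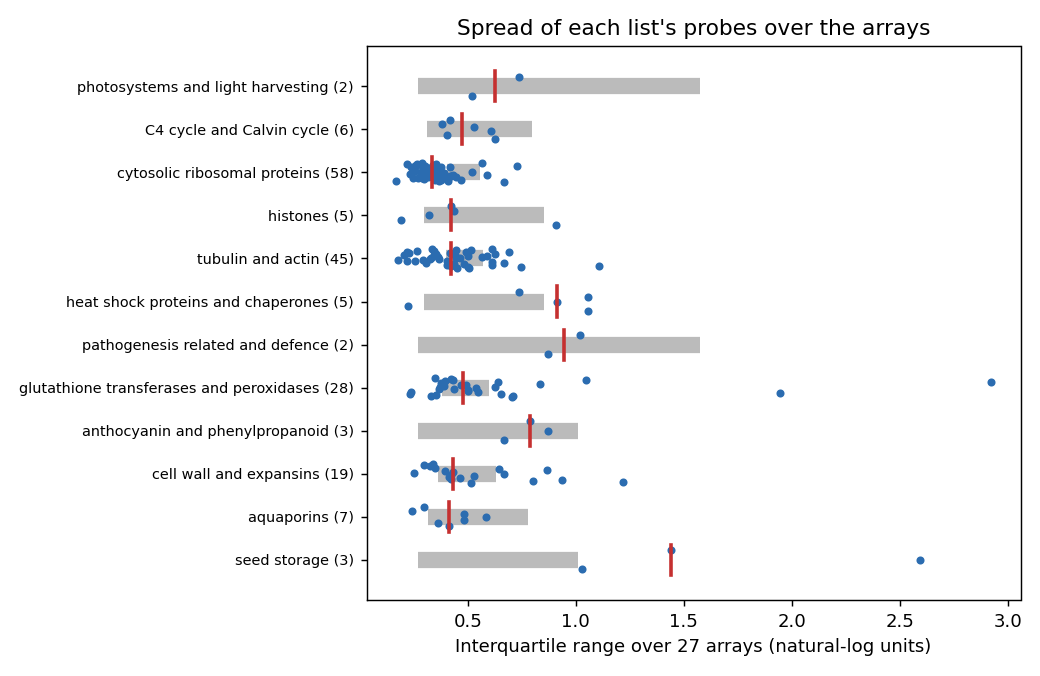
Interquartile range over the 27 arrays, in natural-log units, for the probes of each gene list; points are probes, red bars list medians and grey bars the central 95% of 10000 random lists of the same size, with the number of probes in parentheses. The ribosomal median of 0.337 lies below its grey bar, and the heat shock median of 0.916 and the seed list's of 1.44 lie above theirs.

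On array 1, which carried F1 RNA in Cy3, the named probe with the lowest value was LOC542547 (probe 17453), at -8.38 natural-log units from the array's median. The starch branching enzyme gene sbe1 (probe 18657) followed at -7.52, ark (probe 18544) at -7.05, the pyruvate dehydrogenase gene PDHE1-B (probe 18599) at -6.84 and the Polycomb group gene fie2 (probe 5963) at -6.80. The highest named values were 4.60 for M8 (probe 3975), 4.48 for GIF2 (probe 16979), 4.04 for ys1 (probe 9543), the transporter of iron-phytosiderophores, 3.92 for gst18 and 3.77 for nas1. All but ys1 held the most frequent value on at least 1 array of the series. With runs centred the 5 were at 4.62, 4.81, 4.10, 3.82 and 3.75, and the mir3 probe, in the last run and noted after the values were seen, went from 3.62 to 6.05. The listed tubulin probes were mostly below the array's median, with 35 of 45 below 0. The listed ribosomal protein probes were mostly above it, with 40 of 58 above 0. The counts were 40 of 45 and 32 of 58 once each run of 400 consecutive spot numbers was centred on its own median. No genotype can be given to either side.

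A total of 1459 probes (7.97%) had a value on array 1 outside the range of the other 26 arrays, 895 of them below and 564 above. The mean share over all arrays is 7.41% by construction, since each probe has a lowest and a highest array. The share of array 1 was therefore not tested against chance. Single arrays ran from 1.11% on array 7 to 23.5% on array 19. The interquartile range over probes was 0.376 on array 7, 1.08 on array 19 and 0.599 on array 1. The probes for sbe1, ark and PDHE1-B lay in run 47 of spot numbers, whose median on this array was -1.64. Centred on that run, they were at -5.88, -5.40 and -5.19. By the loop design other arrays also carried F1 RNA, but array 1 is the only one labelled so. The range of the other 26 arrays is therefore not a range without the F1, and the values could not be checked against a labelled replicate.

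**Figure D4:**
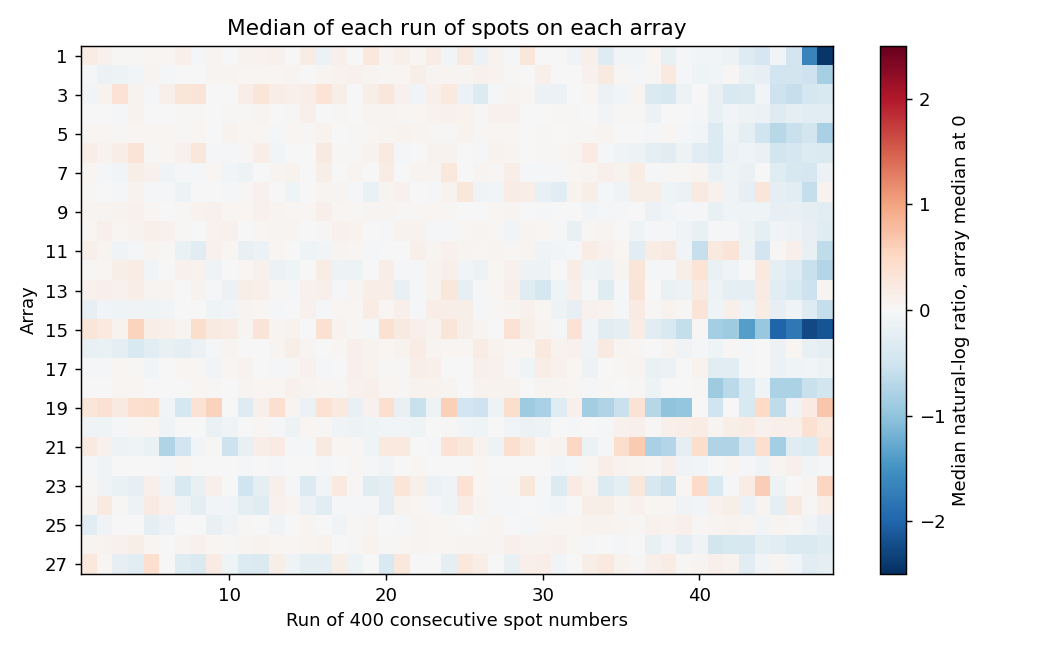
Median natural-log ratio of each of 48 runs of 400 consecutive spot numbers (horizontal axis) on each of the 27 arrays (vertical axis), with each array's median at 0. Array 1 reaches -2.42 in the last run and array 15 reaches -2.26 in run 47.

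On array 17, which carried Mo17 RNA in Cy5, bt1 (probe 16185) had the lowest named value, -4.33. CNX (probe 4445) was at -2.83, the aquaporin-like gene NIP3-1 (probe 13341) at -1.98, der4 (probe 3128) at -1.69 and KIN9 (probe 15403) at -1.63. The highest was the aldehyde dehydrogenase gene rf2b (probe 10393), at 5.39, the highest value of that probe on any array. The elongation factor gene EF1A (probe 4473) was at 2.76, the phosphotransfer protein gene hp2 (probe 13827) at 0.98, the MADS-box gene zmm27 (probe 5971) at 0.95 and a haemoglobin probe (12334) at 0.93. The other haemoglobin probe (16265) was at -0.99. Tubulin probes were evenly placed, with 22 above and 23 below 0, and 23 of the 58 ribosomal probes were above 0.

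On this array 506 probes (2.76%) lay outside the range of the other 26 arrays, 194 below and 312 above. With each array divided by its median absolute deviation the number was 1542 (8.42%), and with quantile normalization 2061. All 5 of the lowest named probes, and rf2b, EF1A and the haemoglobin probe among the highest, held the most frequent value on at least 1 array of the series.

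Across the 18303 probes, correlations between the 27 arrays were mostly low. The median Pearson correlation over all pairs of arrays was 0.050, with a range of -0.27 to 0.50, and 102 pairs lay below 0. Arrays 20 and 22 were the closest pair, at 0.50, and 9 pairs were above 0.3 and 0 below -0.3. Spearman correlations put 29 pairs above 0.3 and 8 below -0.3. These correlations run across probes, which are not independent replicates. Dye-balanced loops pair the genotypes differently and in both directions, so a median near 0 over all pairs does not show that genotypes differ little. In a principal component analysis, 8 components exceeded the same component in 100 matrices in which each probe's values were permuted over the arrays, and the first held 14.2% of the variance against at most 4.55%. The permutation evens out the spread of the arrays, whose interquartile range over probes ran from 0.263 on array 9 to 1.08 on array 19. A widely spread array can therefore exceed a permuted share without another array sharing its values. The count was 8 with each array divided by its median absolute deviation and 6 with quantile normalization. A contrast of 3 genotypes has 2 dimensions, but the 8 are not a count of dimensions shared by the arrays.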

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

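Tests by most frequent value, centred runs, arrays left out and the hsp70-4 addition were chosen after seeing the data. The 842 wide probes became 1752 with the standard deviation, 2161 at 2 times the median and 250 among probes that never held the most frequent value. They numbered 757 to 908 under the other settings and 809 to 891 with each array left out in turn. The median correlation of 0.050 became 0.091 with Spearman correlations, 0.033 with runs centred and -0.038 with each probe centred on its mean. The 9 pairs of arrays above 0.3 became 29 with Spearman correlations and 5 with quantile normalization. They became 3 with each probe centred on its mean and 18 without probes at the most frequent value. The 0 pairs below -0.3 became 8 with Spearman correlations, 2 with centred probes and 6 without probes at the most frequent value. Leaving arrays uncentred or dividing by the median absolute deviation cannot change a Pearson correlation. The 8 components were 6 to 8 under all settings run, and 7 to 8 with each array left out. The 1459 probes of array 1 ranged from 1047 to 1710. The 506 of array 17 became 1542 with scaled arrays and 2061 with quantile normalization, which widen its narrow spread over probes (0.364 against a median of 0.546 over the arrays). The 2 lists outside the central 95% became 1 with scaled arrays, 1 without probes at the most frequent value, 0 with 1 probe per gene and 3 with runs centred, which added the tubulin list. The setting with 1 probe per gene takes each gene's probe with the largest median size, which favours wide probes. Elsewhere the cause was not tested. The planned restriction to probes of higher mean level was not run, because the values are ratios, and a minimum of 20 arrays removes no probe. Signal over background was not analysed here.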

Other observations

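In this part, the comparison of probes of the same gene inside and outside the last runs of array 1, and the ranges without values at the most frequent value, were set before their results were seen; the other tests were chosen after.

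Probes of the same gene varied together, though weakly. Over the 242 genes with at least 2 probes that never held the most frequent value, the median correlation between a gene's probes was 0.125 with runs centred, against at most 0.0337 in 100 shuffles of the gene names. The value was above 0 for 169 genes and below 0 for 73, down to -0.809 for IPP, which had 2 probes. The 6 probes of the glyceraldehyde-3-phosphate dehydrogenase gene GAPC1 had a median correlation of 0.588, the 8 probes of the cell wall glycoprotein gene HRGP 0.571 and the 6 of the sucrose synthase gene sh1 0.537. Genes with 6 to 8 probes also lay below 0. Among them were lim1 with 7 probes at -0.097, the superoxide dismutase gene sod3 with 6 at -0.064 and the enolase gene eno2 with 8 at -0.024. MNB1b, whose assignment looks doubtful, was among the 242 genes, with 218 probes at 0.242. A set of probes that may not be 1 gene thus also lay above the median. These values are consistent with a signal of the RNA shared by a gene's probes, which cross-hybridising relatives could share too.

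The wide probes were set against the lowest signal and against position. Of the 842, 73.6% held their array's most frequent value at least once, against 3.38% of other probes, but on 11 arrays that value lies far from 0 and could widen a range by itself. With the values at it left out, 602 of the 620 wide probes that had held it (97.1%) stayed above the same cutoff. This could not decide the question for the 11 arrays, to which no test was limited. Of the wide probes, 554 held the value on an array where it lies within 0.4 of 0. Leaving out a value there can itself widen a range. Noise between channels near the lowest signal remains a candidate explanation for these probes, bt1, der4 and CNX among those that held the value, as far as the value marks that signal. With each run centred, 729 of the 842 (86.6%) stayed above the same cutoff, and 158 of the 222 that never held the value. That share lies between the bounds set for position along the runs as the cause and as not the cause, so position cannot be told apart for these probes. The 222 wide probes that never held the value, cpi2 and GLN6 among them, stay open. No biological explanation was tested for them.

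Low values on array 1 gathered in the last 2 runs, which held 147 of its 200 lowest probes and 4.20% of all measured probes. For 26 genes with probes there and elsewhere, the probe in the last runs was lower in 24, with a median difference of -1.75 natural-log units (quartiles -2.80 and -1.26). The low values therefore may come from position on the slide. RNA levels of the genes printed there are argued against as the main source, as far as a gene's probes report the same RNA. Such probes varied together only weakly over the arrays, at a median correlation of 0.125 with runs centred, which limits this comparison. The run's median does not account for single probes such as that of ark, which was at -7.05 and stayed at -5.40 with runs centred. On the same array the 2 ark probes outside these runs had a median of 0.076, and the 2 of PDHE1-B had 0.502. The low values of ark and PDHE1-B were thus not shared by other probes of these genes. A difference between the F1 and its partner on this array was not tested.

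Among the 250 widest probes that never held the most frequent value, 3 components exceeded their permuted values. The leading profile over the arrays took 17.98% of the variance, against at most 7.73% after permutation, and the second component 10.3%. Here too the permutation evens out the spread of the arrays. Over all 17093 probes that never held the value, the leading profile correlated above 0.8 in size with 109, 97 positively and 12 negatively, against 0 in 20 permuted matrices. The 250 probes that formed the profile are among the 17093 and were not counted apart, so some of the 109 correlate partly with themselves. Named probes among the 109 were psaH (2377), the aprl8 gene (7602), opr5 (4726), an oxophytodienoate reductase gene, 2 probes of LOC100125656 and, in the opposite sense, the tubulin gene tub6 (11764). A constant dye effect cannot form a profile centred over the arrays. One of 1 sign whose strength varied is argued against, since these probes, before any centring of probes, had values on the more frequent side of 0 on a median of 15 of 27 arrays. For position, the profile correlated at 0.998 with itself after runs were centred, and the 109 probes lay in 36 runs. Run medians were mostly small beside the ranges of the 250 probes, so centring could hardly change the profile. Position within a run was not tested, and no conclusion about position is drawn. For artefacts of single spots, 5 other probes of 3 of these genes had a median correlation of 0.654 with the profile. The 4 of LOC100125656 and tub6 exceeded 0.3, from 0.648 to 0.794, which argues against such artefacts for these 2 genes. Their probes among the 109 had ranges of at most 0.955 and were not among the 250. The aprl8 probe 7602 had a range of 1.51, but the other aprl8 probe was at -0.027. Only 6 of the 109 probes are named, so most could not be checked this way. A difference between the genotypes may also give such a profile, but it cannot be told apart with 2 labelled channels of 54.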
